A study of Rattus norvegicus with 38 samples.

How the data were processed

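RNA sequencing was analysed from 38 livers of Sprague-Dawley rats, a common outbred laboratory strain, taken on day 28. Per the labels, 3 extracts named only EF, PF and RD were given into the stomach. The dose of RD was 200 mg/kg, and EF and PF had a dose of 2.5 g/kg each. Lipopolysaccharide (LPS), the outer membrane component of gram-negative bacteria that sets off inflammation, was injected into the abdominal cavity. The dose of LPS and the time between its injection and the collection of the livers are not given in the sources used here. The 8 groups form a layout of LPS or no LPS by no extract, EF, EF with PF, or EF with RD. They are called control (n = 5), EF (n = 5), EF_PF (n = 5), EF_RD (n = 4), LPS (n = 5), LPS_EF (n = 5), LPS_EF_PF (n = 4) and LPS_EF_RD (n = 5). The design text calls the samples biological replicates. PF and RD were given only together with EF, so EF_PF or EF_RD against EF tests what PF or RD added to EF, and their own effects were not tested. All samples carry 1 batch label. The labels name hepatocytes as the cell type and liver as the source, and no step that would separate hepatocytes is described in the labels' protocols. RNA was extracted and libraries were built with commercial kits, per the labels' protocols.

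The deposited count table holds whole numbers of read pairs per gene name for 31038 genes. Per the file headers, the authors counted read pairs with featureCounts 2.0.6, grouped by gene name, with a RefSeq annotation of the rat genome build rn6, and with no strand setting and no option for reads that map to several places. Reads of a gene and of an overlapping antisense gene could therefore not be told apart, and members of near-identical families, such as Mt1 and Mt2A, the Cyp2b, Cyp2c and Ces2 genes and ribosomal protein genes with many pseudogenes, are uncertain because reads shared between copies were left out under that setting. The submitters' processing notes also name STAR, RSEM and the build mRatBN7.2. The positions printed here are those of the count table and its header names rn6, so they are given as rn6; the difference between the sources was left open. A gene name on 2 or more chromosomes was counted as 1 gene in the table, which held for 18 names. A count of 0 in all libraries was found for 7071 genes.

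The deposited TPM table was checked against the counts. For 31011 gene names found in both, TPM was recomputed as counts divided by gene length and scaled to the same total in each library. Over 432779 values of 1 TPM or more, the largest relative difference was 0.0495%, inside a tolerance of 1%, in all 38 columns. The authors' TPM values are thus length-scaled counts, and 27 names were not matched. TPM was used only in alternative fits. Every column was matched to 1 sample by its name, and 0 columns were left over.

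The total of counted read pairs per library ran from 19716622 to 35835012. No molecular identifiers are described, so read pairs are not independent molecules.

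Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, which left 14786 genes. Library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model (glmQLFit and glmQLFTest) with 1 mean per group was fitted to all 38 libraries at once, so that the 17 comparisons share 1 estimate of the spread. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 17 comparisons are LPS against control, each extract treatment against control, each extract treatment with LPS against LPS, each combination against EF with and without LPS, LPS against no LPS within each extract treatment, and the 3 interactions of LPS with an extract treatment. Log2 fold changes are given with standard errors. Levels are CPM, the deposited counts scaled to a common library size by TMM. The total count as the scaling factor was used once to see how far the scaling moves the median gene.

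In all, 32 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry stand beside it. The lists cover inflammation, drug metabolism, lipid, bile acid, glucose and amino acid metabolism, stress, proliferation, the circadian clock, growth hormone and sex-biased genes, secreted liver proteins, markers of the cell types of liver and blood, markers of pancreas and of other tissues, mitochondrially encoded genes and ribosomal protein genes. Lists of 22 skeletal muscle and 14 exocrine pancreas markers were added after the marker levels were seen. The number of members called up and down is given over all genes tested and adjusted over the list alone.

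The genes named in the text were chosen by a rule. Among called genes with a mean of at least 2 CPM in the higher group and a proper gene symbol, the 6 largest rises and 6 largest falls were taken, and the 2 members with the smallest adjusted p of each of the 8 lists with the smallest camera p. For comparisons against EF, for LPS within an extract treatment and for interactions, the 5 genes with the smallest adjusted p and members from 4 lists were taken. Where no gene passed, the 3 with the smallest p were taken. A fixed panel of 15 genes was added. Genes named outside the rule are marked as such. Some genes that the rule or the panel names are not reported here. Where a group held 3 or fewer counts of a gene, the ratio of the groups is given with its exact 95% interval, which covers counting error only.

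The comparisons, the test, the 32 lists, the rule and all alternatives except 3 were chosen before the data were examined. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1) with a filter of 0.5 TPM in 4 libraries or none, voom with sample weights, a fit to only the groups compared, and each library left out in turn. The 3 added after seeing the data leave out the 3 libraries with RNA of other tissues (control 5, LPS 3 and EF_RD 1), leave out 2 LPS-injected libraries with little LPS response (LPS_EF 7 and LPS_EF_RD 6), and add a clock covariate, the log2 ratio of Arntl to Dbp.

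The test was run on simulated data for 2 comparisons, with counts drawn for the 14786 genes from the real means and library sizes and 200 genes with a mean of at least 1 CPM changed. For EF against control, 55.2% of changes of 1.5-fold, 88.1% of 2-fold and 97% of 4-fold were recovered, with 9 false calls among 169. For EF_RD against control these shares were 43.3%, 80.6% and 95.5%, with 9 false calls among 155. The simulated genes varied independently of each other, without RNA of other tissues. These shares and false calls therefore need not hold for the real libraries, where other splits of EF and control called up to 1318 genes. No pair of libraries differed by less than sampling noise: the lowest chi-square per degree of freedom was 5.69 among the 72 pairs within a group and 27.1 among the 631 pairs between groups. Comparisons that share control libraries share chance values, so 10 simulations of unchanged groups and splits of the controls are given beside each overlap. To see how often other groupings give as many calls, up to 100 splits of the same libraries were refitted for each comparison.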

Results

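RNA of 38 rat livers collected on day 28 was counted per gene in 8 groups, which cross an injection of LPS with no extract, EF, EF with PF, or EF with RD. The libraries held 21563143 to 27076278 counted read pairs in control (n = 5), 21682021 to 27935596 in EF (n = 5), 22287849 to 25422925 in EF_PF (n = 5) and 22676765 to 26790887 in EF_RD (n = 4). After LPS they held 23482464 to 27121056 in LPS (n = 5), 25447830 to 27073411 in LPS_EF (n = 5), 23371592 to 35835012 in LPS_EF_PF (n = 4) and 19716622 to 27986310 in LPS_EF_RD (n = 5). Between 12969 and 14658 genes had at least 10 counts per library. Mitochondrially encoded genes took 3.08% to 4.52% of the counts, and the 10 most abundant genes 22.7% to 27.5%. The first principal component of log2 CPM held 40.8% of the variance and the second 8.37%. Libraries are named by group and replicate number. Fold changes are log2 values with their standard error (SE). Adjusted p-values of genes are those of edgeR's quasi-likelihood test, and levels are mean CPM with their SD.

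The first comparison asks how LPS changed the liver without an extract. A2m, a protease inhibitor of the rat acute phase (rn6 chromosome 4, 154309426 to 154359138), rose from 1.32 ± 0.592 CPM in 5 control livers to 205 ± 84.1 CPM in 5 LPS livers. Its log2 fold change was 7.27 ± 0.97 (adjusted p = 2.78e-06). Lbp, the plasma protein that binds LPS, rose from 135 ± 20.9 to 2854 ± 576 CPM (4.41 ± 0.54, adjusted p = 1.54e-06). Among the genes that fell, Sds, which degrades serine, went from 424 ± 259 to 34.5 ± 31.1 CPM (−3.62 ± 0.97, adjusted p = 0.00399). Cps1, the entry enzyme of the urea cycle, went from 5682 ± 677 to 2367 ± 472 CPM (−1.26 ± 0.2, adjusted p = 1.73e-05). In all, 5435 of 14786 genes were called, 2752 higher and 2683 lower, and 1296 were at least 2-fold higher and 329 at least 2-fold lower. With the replicate number as a block 3565 were called.

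The largest rises included Lcn2, an iron-sequestering protein (chromosome 3, 11414189 to 11417534), at 9.74 ± 1.97 (adjusted p = 0.000291), which ran from 26.8 to 2270 CPM within the LPS group. Gucy2c, a membrane guanylate cyclase (chromosome 4, 170659993 to 170740274), had 1883 counts in LPS against 2 in control (adjusted p = 1.86e-06). Their ratio was 835, with a 95% counting interval of 231 to 6900. Mmp3, a matrix protease (chromosome 8, 5676608 to 5698579), had 612 counts against 3 (adjusted p = 7.07e-06), a ratio of 181 with an interval of 61.6 to 880. S100a8, a neutrophil calcium-binding protein (chromosome 2, 190073239 to 190074333), rose by 5.23 ± 0.73 and Ncf1, a subunit of the phagocyte oxidase, by 3.67 ± 0.42. The largest falls were Nxpe5 at −4.41 ± 0.69, Sds, Tsku at −3.6 ± 0.88, Mmd2 at −3.03 ± 0.69, Noct, the rhythmically expressed nocturnin, at −2.96 ± 0.86, and Gabrp at −2.96 ± 0.93. The call of Gabrp was lost without control 5 (adjusted p = 0.77). Atp2a1, the calcium pump of fast skeletal muscle, was also called (5.92 ± 1.84, adjusted p = 0.0119), with 9.14 ± 19.9 CPM in LPS. Without LPS 3 or without LPS 4 it fell under the low-count filter and was not tested. Nqo1, a quinone reductase, rose by 1 ± 0.32 (adjusted p = 0.0127), a call lost without LPS 1 (adjusted p = 0.0745).

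**Figure D1:**
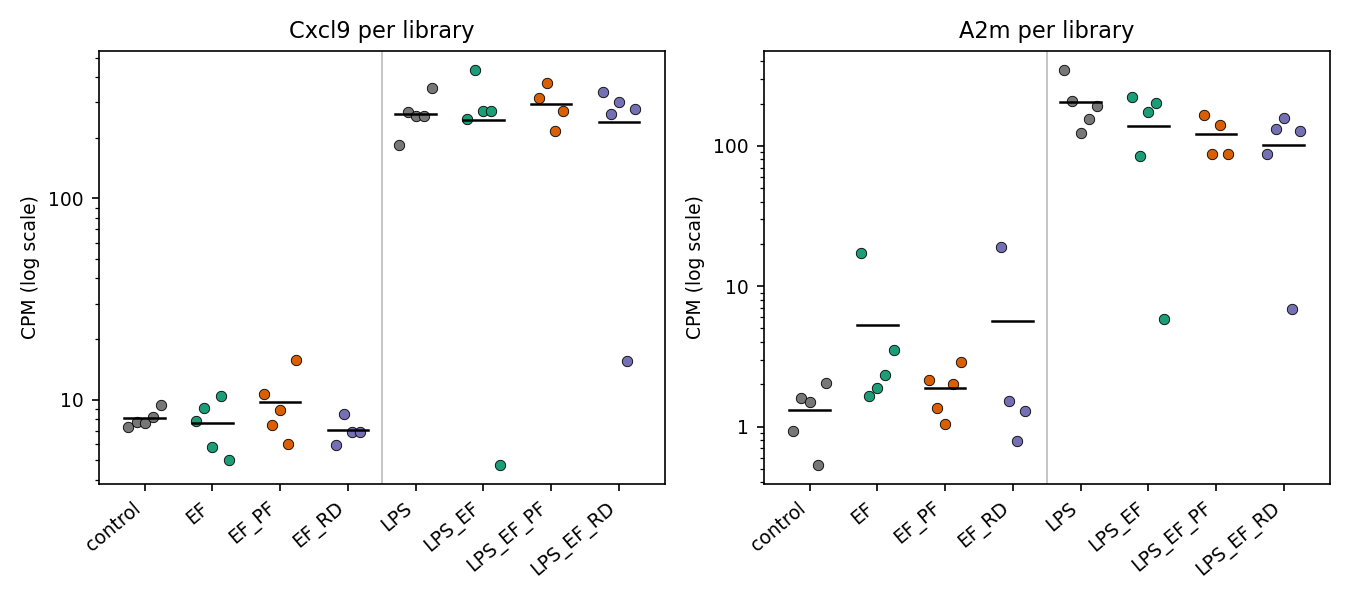
Levels of Cxcl9, an interferon-induced chemokine, and A2m in each of the 38 livers by group, as CPM on a log axis, where each point is a library and each black line a group mean. Cxcl9 lay between 185 and 354 CPM in the LPS group, while LPS_EF 7 at 4.75 CPM and LPS_EF_RD 6 at 15.6 CPM lay under the highest value without LPS, 15.8 CPM.

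By gene group, 14 of 22 acute-phase genes were called higher after LPS and 1 lower (16 and 1 adjusted over the list alone). Of 15 neutrophil and monocyte markers 14 were higher (14 adjusted over the list alone), with a median log2 fold change of 2.96. Both list tests went up, with adjusted p = 1.06e-05 and 4.17e-10, and with adjusted p = 0.356 for both with an estimated correlation. Cytokines and adhesion molecules had 8 higher and 2 lower of 19 (10 and 2 adjusted over the list alone). Their test gave adjusted p = 0.0139, and adjusted p = 0.418 with an estimated correlation. Among 21 NF-kB targets 8 were higher (8 adjusted over the list alone), and the list test gave adjusted p = 0.0784. Interferon-stimulated genes had 5 higher and 13 lower of 29 (5 and 13 adjusted over the list alone), with a median of −0.44 (adjusted p = 0.0334, and adjusted p = 0.664 with an estimated correlation). That list call was lost in 5 omissions, with the highest adjusted p of 0.0616 without LPS 3.

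Markers of endothelial, Kupffer, stellate and lymphoid cells went up with LPS, and each list call was lost with an estimated correlation. Of 15 endothelial genes 10 were higher (10, and 1 lower, adjusted over the list alone), such as Pecam1 at 1.23 ± 0.19 and Eng at 1.12 ± 0.14. The list gave adjusted p = 4.33e-05, and adjusted p = 0.356 with an estimated correlation. Of 17 Kupffer cell and macrophage markers 9 were higher (10 adjusted over the list alone), with Cd14, the LPS co-receptor, at 1.89 ± 0.24. Their test gave adjusted p = 0.000723, and adjusted p = 0.505 with an estimated correlation. Stellate cell and fibrosis markers had 11 higher of 20 (11 adjusted over the list alone), and lymphocyte markers 9 higher and 1 lower of 18 (9 and 1 adjusted over the list alone). These tests gave adjusted p = 0.000202 and 0.0122, and adjusted p = 0.418 and 0.516 with an estimated correlation.

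Of 21 gluconeogenesis and amino acid genes 15 fell (16 adjusted over the list alone), with a median of −1.03, and Pc, pyruvate carboxylase, stood at −0.97 ± 0.15. Of 30 PPARα and fatty acid oxidation genes 18 fell (20 adjusted over the list alone), among them Acadm at −0.91 ± 0.13 and Etfdh at −0.81 ± 0.12. The 2 lists had adjusted p = 4.63e-07 and 5.1e-07, and adjusted p = 0.356 each with an estimated correlation. Cpt1a, the carnitine shuttle enzyme, was called lower (−0.78 ± 0.26, adjusted p = 0.0189). Leaving out control 4, control 6, LPS 2 or LPS 3 lost that call, with the highest adjusted p of 0.0889 without control 6. Cholesterol synthesis went the other way. There 19 of 25 genes rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.07 (adjusted p = 1.86e-08, and adjusted p = 0.356 with an estimated correlation). Msmo1, a sterol methyl oxidase (chromosome 16, 26859441 to 26875880), rose by 1.97 ± 0.3 and Sqle, squalene epoxidase (chromosome 7, 99609929 to 99624803), by 1.88 ± 0.28. Lipogenesis had 9 lower of 20 (11 adjusted over the list alone), with adjusted p = 0.014, and adjusted p = 0.505 with an estimated correlation. That list call was lost without control 3 (adjusted p = 0.111). Bile acid genes had 4 higher and 9 lower of 23 (4 and 11 adjusted over the list alone), and CAR and PXR targets 7 lower of 19 (8 adjusted over the list alone). Both tests went down, with adjusted p = 0.0204 and 0.0129, and adjusted p = 0.395 and 0.418 with an estimated correlation.

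Hepatocyte markers had 13 lower of 19 (15, and 1 higher, adjusted over the list alone), with Alb, albumin, at −0.47 ± 0.15 and Rbp4 at −0.76 ± 0.14. The call of Alb was lost in 4 of 11 alternatives, with the replicate block and in the 3 fits on TPM (highest adjusted p = 0.672). Growth hormone and IGF genes had 6 lower of 15 (9 adjusted over the list alone), and male-biased genes 6 of 10 (6 adjusted over the list alone). The 3 lists had adjusted p = 3.76e-05, 0.0117 and 0.00209, and adjusted p = 0.356 each with an estimated correlation. Cyp2c11, the male-specific steroid hydroxylase (chromosome 1, 257676172 to 258004428), fell from 1579 ± 230 to 718 ± 255 CPM (−1.14 ± 0.36, adjusted p = 0.0134). Heat shock genes had 8 lower of 16 (9 adjusted over the list alone), with adjusted p = 0.00309, and adjusted p = 0.395 with an estimated correlation. Ribosomal protein genes had 19 higher of 71 (16 adjusted over the list alone), with Rpl3 at 0.57 ± 0.12 and Rps26 at 0.46 ± 0.12. Their test gave adjusted p = 0.000109, and adjusted p = 0.664 with an estimated correlation.

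The remaining lists did not pass their test after LPS. Nrf2 targets had 4 higher and 8 lower of 21 (adjusted p = 0.217), complement and coagulation genes 5 and 11 of 34 (0.14), ER stress genes 10 and 7 of 23 (0.573) and p53 targets 4 and 4 of 20 (0.811). Proliferation had 7 higher of 28 (4 adjusted over the list alone, adjusted p = 0.0672), cholangiocyte markers 3 lower of 13 (0.262), AhR targets 1 and 1 of 7 (0.923) and mitochondrially encoded genes 2 lower of 13 (0 adjusted over the list alone, adjusted p = 0.923). No gene was called among female-biased genes (adjusted p = 0.353), clock genes (0.556), erythroid markers (0.576) or markers of pancreas and other tissues (0.573). The AhR test went down with a median of 0.10, the ER stress test up with a median of 0.27 and a mean of −0.05, and the mitochondrial test down with a median of 0.04. Of the added lists, 6 of 9 tested muscle markers were called higher and 0 of 9 tested pancreas markers were called. LPS 3 held 573 CPM of muscle and 1980 CPM of pancreas markers. Scaling by total counts in place of TMM moved the median gene from −0.002 to 0.128 and the share of higher genes among those called from 50.6% to 72%.

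LPS was next compared with no LPS within each extract treatment. A2m rose by 4.7 ± 0.84 in LPS_EF against EF (adjusted p = 0.000124), by 5.99 ± 0.92 in LPS_EF_PF against EF_PF (adjusted p = 1.29e-05) and by 4.18 ± 0.9 in LPS_EF_RD against EF_RD (adjusted p = 0.00133). Its level was 138 ± 90.8 CPM in LPS_EF, 120 ± 40.3 in LPS_EF_PF and 102 ± 58.7 in LPS_EF_RD. These means include LPS_EF 7 at 5.84 and LPS_EF_RD 6 at 6.9 CPM. Without LPS, EF 1 stood at 17.2 and EF_RD 1 at 19 CPM, and without these libraries the log2 fold change was 5.871 with EF and 6.403 with EF_RD. Siglec10, an inhibitory receptor of immune cells (chromosome 1, 98512663 to 98521736), rose by 5.34 ± 0.55, 5.93 ± 0.54 and 4.57 ± 0.56. Ncf1 rose by 2.37 ± 0.39, 3.62 ± 0.43 and 3.44 ± 0.45, and Lcn2 by 6.11 ± 1.65, 9.09 ± 2.01 and 7.98 ± 2. Lcn2 depended on single libraries, at 8.21 without EF 1, 5.95 without LPS_EF_PF 6 and 10.395 without EF_RD 1, and its call was kept in every omission. Voom lost it in the EF_PF arm (adjusted p = 0.0898) and for LPS against control (adjusted p = 0.109). With EF 4310 genes were called (2164 higher, 2146 lower), with EF_PF 5402 (2839 and 2563) and with EF_RD 3470 (1889 and 1581). In all 4 arms, control included, 1117 genes were called higher and 677 lower.

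Within the EF arm endothelial markers rose, 13 of 15 (13 adjusted over the list alone), with Pde2a at 1.33 ± 0.16 and Gpr182 at 1.02 ± 0.13. Neutrophil and monocyte markers had 13 higher of 15 (14 adjusted over the list alone), and ribosomal protein genes 30 of 71 (41 adjusted over the list alone). The 3 lists had adjusted p = 2.69e-08, 3.83e-08 and 1.03e-09, and adjusted p = 0.333, 0.507 and 0.517 with an estimated correlation. Cyp2c11 fell by 2.08 ± 0.37 (adjusted p = 0.000128) and Cyp3a9, a steroid and drug hydroxylase, by 0.98 ± 0.28. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.93 ± 0.53 (adjusted p = 0.00661), a call lost without EF 2 (adjusted p = 0.0559). Cholesterol synthesis went down with 4 of 25 lower (2 adjusted over the list alone), at adjusted p = 0.022, and adjusted p = 0.705 with an estimated correlation. That list call was lost without LPS_EF 7 (adjusted p = 0.229), EF 1 (0.146) or EF 3 (0.0517).

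With EF_PF, Cyp2c11 fell by 3.01 ± 0.42 (adjusted p = 4.31e-06), Lpin1, a phosphatidate phosphatase, by 2.31 ± 0.41 and Fads2, a fatty acid desaturase, by 1.85 ± 0.31. Tlr2, a receptor for bacterial lipoproteins, rose by 3.3 ± 0.35. Hepatocyte markers had 16 lower of 19 (16, and 1 higher, adjusted over the list alone), lipogenesis 14 of 20 (14 adjusted over the list alone) and cholesterol synthesis 6 of 25 (6 adjusted over the list alone). These lists had adjusted p = 5.01e-06, 5.01e-06 and 0.000841, and adjusted p = 0.278, 0.278 and 0.549 with an estimated correlation. Cyp1a2, a drug oxidase, fell by 1.04 ± 0.27 (adjusted p = 0.00298). Single omissions lost the calls of Alb (−0.44 ± 0.16, 3 omissions, highest adjusted p = 0.0571 without EF_PF 1) and Cyp1a1 (−1.36 ± 0.5, 5 omissions, 0.1 without EF_PF 3). They also lost those of Cyp2b1 (−1.97, 5 omissions, 0.1 without LPS_EF_PF 1) and Mki67, a proliferation marker (1.18 ± 0.41, 4 omissions, 0.0938 without LPS_EF_PF 1).

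With EF_RD, PPARα and fatty acid oxidation genes fell, 25 of 30 (26 adjusted over the list alone) with a median of −0.95, among them Decr1 at −0.96 ± 0.14. Proliferation genes rose, 23 of 28 (26 adjusted over the list alone) with a median of 1.38, among them Mki67 at 1.81 ± 0.44 and the replication helicase subunits Mcm3 at 1.75 ± 0.3 and Mcm2 at 0.87 ± 0.15. The 2 lists had adjusted p = 5.44e-16 and 4.02e-11, and adjusted p = 0.23 and 0.251 with an estimated correlation. All 9 tested muscle markers were lower in LPS_EF_RD than in EF_RD, whose library EF_RD 1 held 5350 CPM of muscle markers. Total-count scaling moved the median gene from −0.022 to 0.144 in the EF_PF arm. It moved the share of higher genes from 50.2% to 67.7% with EF, from 52.6% to 78.5% with EF_PF and from 54.4% to 64.7% with EF_RD. Without LPS_EF_RD 2 the EF_RD count was 2288, and without LPS_EF_RD 6, a library with little LPS response, it was 4260. Fitted to only the groups compared, the counts were 2127 with EF and 1692 with EF_RD, and voom called 5704 with EF_RD.

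EF alone was compared with control. Genes of cholesterol synthesis rose together, and so did drug-metabolising Cyp1a2. Msmo1 rose from 128 ± 25.9 to 556 ± 227 CPM (n = 5 and 5, 2.11 ± 0.3, adjusted p = 0.000131). Hmgcs1, the entry enzyme of the mevalonate pathway (chromosome 2, 52427351 to 52445082), rose from 481 ± 73.6 to 1783 ± 617 CPM (1.89 ± 0.27, adjusted p = 0.000131). Of 25 cholesterol synthesis genes 18 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median of 1.06 (adjusted p = 5.59e-44, and adjusted p = 0.0137 with an estimated correlation). Cyp1a2 (chromosome 8, 62451360 to 62458244) rose from 374 ± 67.6 to 1208 ± 391 CPM (1.69 ± 0.26, adjusted p = 0.000273). The 7 AhR targets had 1 higher (3 adjusted over the list alone, adjusted p = 0.00248, and adjusted p = 0.0206 with an estimated correlation). Mt2A, a metal-binding metallothionein (chromosome 19, 11307966 to 11308740), rose from 31 ± 16.2 to 209 ± 165 CPM (2.75 ± 0.52, adjusted p = 0.00546), and Aacs, which activates acetoacetate, by 2.18 ± 0.4. Ppp1r3g, a glycogen-targeting phosphatase subunit (chromosome 17, 29566032 to 29570294), fell from 4.77 ± 2.69 to 0.845 ± 0.487 CPM (−2.5 ± 0.52, adjusted p = 0.0107), a call lost without control 4 (adjusted p = 0.0544). Cyp4f39 fell by 1.37 ± 0.28 (adjusted p = 0.00826).

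In all, 136 genes were called with EF, 97 higher and 39 lower, and 57 and 15 of these were at least 2-fold changed. Other named calls depended on single libraries, here with the number of omissions that lost the call and the highest adjusted p. These were Kng1 (2.11 ± 0.46, 4 omissions, 0.115 without EF 1), Cyp2c6v1 (0.68 ± 0.15, 2 omissions, 0.0715 without control 6) and Ccnd1, cyclin D1 (−1.92 ± 0.48, 6 omissions, 0.123 without control 4). Further ones were Osmr, the oncostatin M receptor (2.6 ± 0.65, 7 omissions, 0.145 without EF 1), Colq (3.13 ± 0.77, 7 omissions, 0.241 without EF 5) and Cyp2b2 (1.5 ± 0.38, 9 omissions, 0.132 without control 4). The pancreatic enzymes Cel (−10.2 ± 2.6), Ctrc (−8.09 ± 1.96) and Cela2a (−6.93 ± 1.76) were called lower. Control 5 held 3420 CPM of pancreas markers, and without it the adjusted p of these enzymes was 0.969, 0.994 and 0.946. The list of pancreas and other tissues went down with 2 lower of 11 (9 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.755 with an estimated correlation), a call lost without control 5 (adjusted p = 0.996). PPARα genes and acute-phase genes went up with 0 called (3 and 1 higher adjusted over the list alone), at adjusted p = 0.000162 each, and adjusted p = 0.735 with an estimated correlation. EF 1 stood above the other EF livers in A2m (17.2 against 1.64 to 3.51 CPM) and Lcn2 (51.5 against 0.158 to 5.79 CPM), and without it the acute-phase list had adjusted p = 0.0104. CAR and PXR targets went up with 2 higher of 19 (4 adjusted over the list alone) and bile acid genes with 1 of 23 (3 adjusted over the list alone). Their tests gave adjusted p = 0.00508 and 0.0145, and adjusted p = 0.735 each with an estimated correlation. The bile acid call was lost without EF 4 (adjusted p = 0.0532). The count of 136 was 56 without EF 1, 70 without control 4, 80 without EF 5, 83 without control 7, 85 without control 6 and 216 without EF 4. It was 35 in a fit to only these 2 groups, 273 with DESeq2 and 87 with voom.

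**Figure D2:**
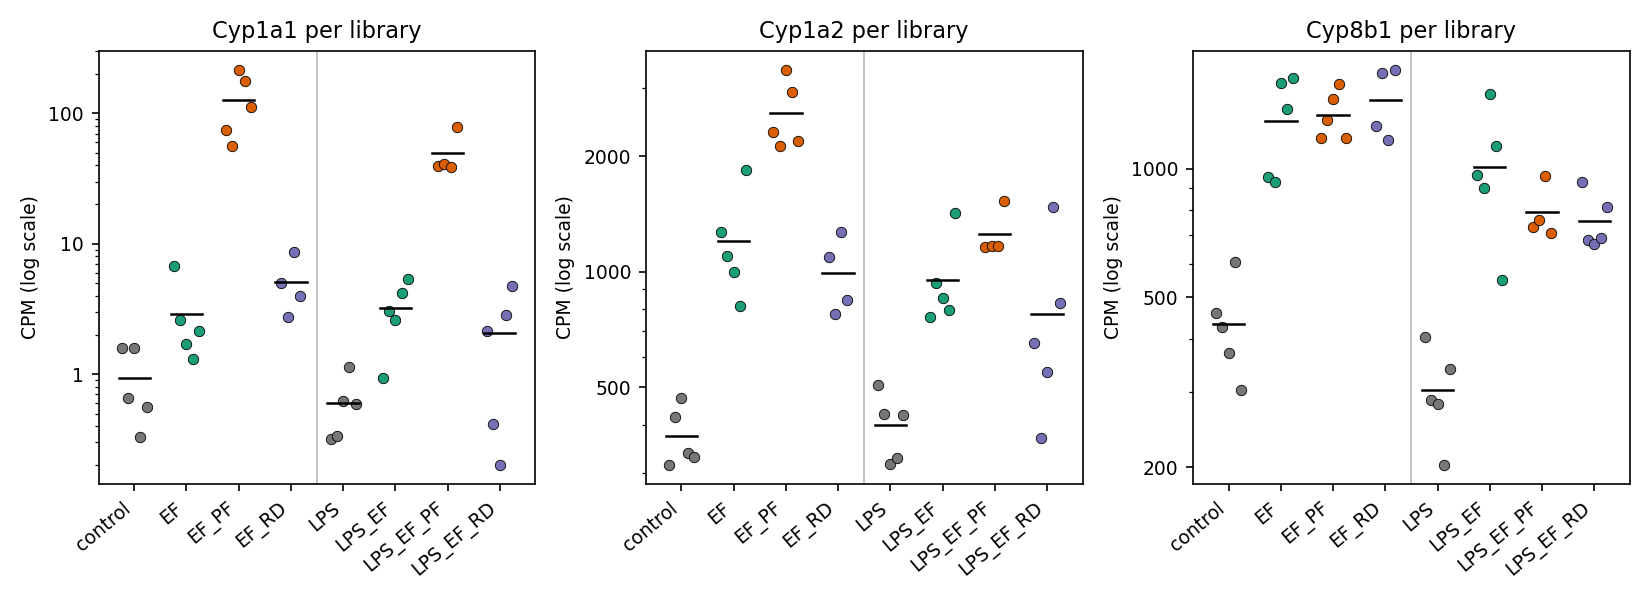
Levels of Cyp1a1, Cyp1a2 and Cyp8b1 in each of the 38 livers by group, as CPM on a log axis, where each point is a library and each black line a group mean. Cyp1a1 lay between 55.7 and 213 CPM in EF_PF, against a mean of 0.942 CPM in control.

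EF with PF was compared with control and with EF alone. Cyp1a1, a target of the aryl hydrocarbon receptor (chromosome 8, 62472087 to 62478122), rose most, from 0.942 ± 0.596 CPM in control to 127 ± 67.2 CPM in EF_PF (n = 5 and 5, 7.09 ± 0.63, adjusted p = 1.22e-08). Cyp1a2 rose from 374 ± 67.6 to 2584 ± 529 CPM (2.79 ± 0.27, adjusted p = 3.08e-08). Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis (chromosome 8, 130548418 to 130550388), rose from 433 ± 114 to 1339 ± 177 CPM (1.63 ± 0.21, adjusted p = 3.49e-05). Srebf2, the transcription factor of cholesterol synthesis, rose by 0.8 ± 0.12 (adjusted p = 0.000378), Tm7sf2, a sterol reductase, by 1.28 ± 0.2 and Fam198a by 1.96 ± 0.37. Crem, a cAMP-responsive transcription factor, fell from 117 ± 13.7 to 59.5 ± 10.8 CPM (−0.98 ± 0.17, adjusted p = 0.00224).

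Of the 7 AhR targets 2 were higher with EF_PF (4 adjusted over the list alone, adjusted p = 6.88e-09, and adjusted p = 3.51e-05 with an estimated correlation). Cholesterol synthesis had 11 higher of 25 (22 adjusted over the list alone) and a median of 0.92 (adjusted p = 2.7e-33, and adjusted p = 0.0279 with an estimated correlation). Bile acid genes had 1 higher of 23 (5 adjusted over the list alone, adjusted p = 4.11e-05, and adjusted p = 0.0974 with an estimated correlation). CAR and PXR targets and Nrf2 targets went up and ER stress genes down with 0 called over all genes, while 4 of 19, 3 of 21 and 4 of 23 passed adjusted over the list alone. The list tests gave adjusted p = 7.71e-05, 0.00043 and 7.71e-05, and adjusted p = 0.219 each with an estimated correlation. Ribosomal protein and mitochondrially encoded genes went up with 1 called each (adjusted p = 1.91e-11 and 0.000267, and adjusted p = 0.57 and 0.455 with an estimated correlation). In all 92 genes were called, 66 higher and 26 lower, 25 and 4 of them at least 2-fold. Single omissions lost the calls of Aacs (1.79 ± 0.4, 4 omissions, highest adjusted p = 0.0846 without control 4) and Ppp1r3g (−2.37 ± 0.52, 5 omissions, 0.088 without control 4). The same held for Mt2A (2.14 ± 0.51, 7 omissions) and Mt1 (2 ± 0.49, 9 omissions), at 0.0994 and 0.109 without control 7. Suco, Uap1, Mgat2, Csrp1, ATP8 and Rps26, with changes of at most 0.66 in size, lost theirs in 6 to 8 omissions. The count of 92 was 39 without EF_PF 5, 43 without control 4 and 61 without EF_PF 2. DESeq2 called 246 and voom 406, and the test without a low-count filter 61.

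Against EF, where Cyp1a1 was at 2.92 ± 2.21 CPM, EF_PF was higher in Cyp1a1 by 5.45 ± 0.57 (adjusted p = 6.07e-07). The AhR list went up with 1 higher of 7 (2 adjusted over the list alone, adjusted p = 0.000942, and adjusted p = 0.0199 with an estimated correlation). Cyp1a2 stood at 1.1 ± 0.25 and missed the threshold (adjusted p = 0.0636). Tomm40l, of the mitochondrial import channel family (0.78 ± 0.15), was higher, and Pp2d1 (−0.61 ± 0.12) and Rab6a, a Golgi transport GTPase (−0.36 ± 0.07), were lower, all at adjusted p = 0.0279. Those 3 calls were lost in 5, 8 and 8 of 10 omissions, with the highest adjusted p of 0.0994 and 0.0994 without EF_PF 2 and of 0.0974 without EF 5. In all 24 genes were called, 10 higher and 14 lower, or 41.7% higher, which total-count scaling moved to 75%. The count was 1 without EF 1 or EF_PF 2, 2 without EF_PF 6, 4 without EF_PF 5, 5 without EF_PF 1 and 6 without EF 5. It was 8 without EF 2, 9 without EF 3, 11 without EF_PF 3 and 73 without EF 4. With the clock covariate, or in a fit to only the 2 groups, it was 1, and DESeq2 called 173.

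EF with RD was compared with control and with EF alone. Cyp1a2 rose from 374 ± 67.6 to 996 ± 229 CPM (n = 5 and 4, 1.41 ± 0.26, adjusted p = 0.0055) and Tm7sf2 by 1.04 ± 0.21 (adjusted p = 0.00664). Ppp1r3g fell from 4.77 ± 2.69 to 0.432 ± 0.364 CPM (−3.43 ± 0.61, adjusted p = 0.00351). Srebf2 rose by 0.58 ± 0.13 (adjusted p = 0.0144), a call lost without EF_RD 1 (adjusted p = 0.0776). Scd, which makes monounsaturated fatty acids (chromosome 1, 264159966 to 264173061), fell from 2236 ± 1420 to 303 ± 289 CPM (−2.89 ± 0.73, adjusted p = 0.0337). The acyl-CoA thioesterases Acot2 (1 ± 0.25) and Acot3 (1.11 ± 0.29) and Cyp1a1 (2.45 ± 0.62) rose. These calls were lost in 5 of 9 omissions for Scd (highest adjusted p = 0.0953 without EF_RD 4), 7 for Acot2 (0.0854 without control 3), 7 for Acot3 (0.117 without EF_RD 4) and 6 for Cyp1a1 (0.0953 without EF_RD 3). Skeletal muscle genes were the largest rises, with Atp2a1 at 9.94 ± 1.88, Tnnt3 at 8.64 ± 1.67, Neb at 7.68 ± 1.56, Actn3 at 7.63 ± 1.44 and Ttn at 7.5 ± 1.43. H19, an imprinted non-coding RNA, stood at 7.13 ± 1.4. Without EF_RD 1 the adjusted p of these 6 genes was 0.806, 0.988, 0.984, 0.893, 0.835 and 0.649.

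**Figure D3:**
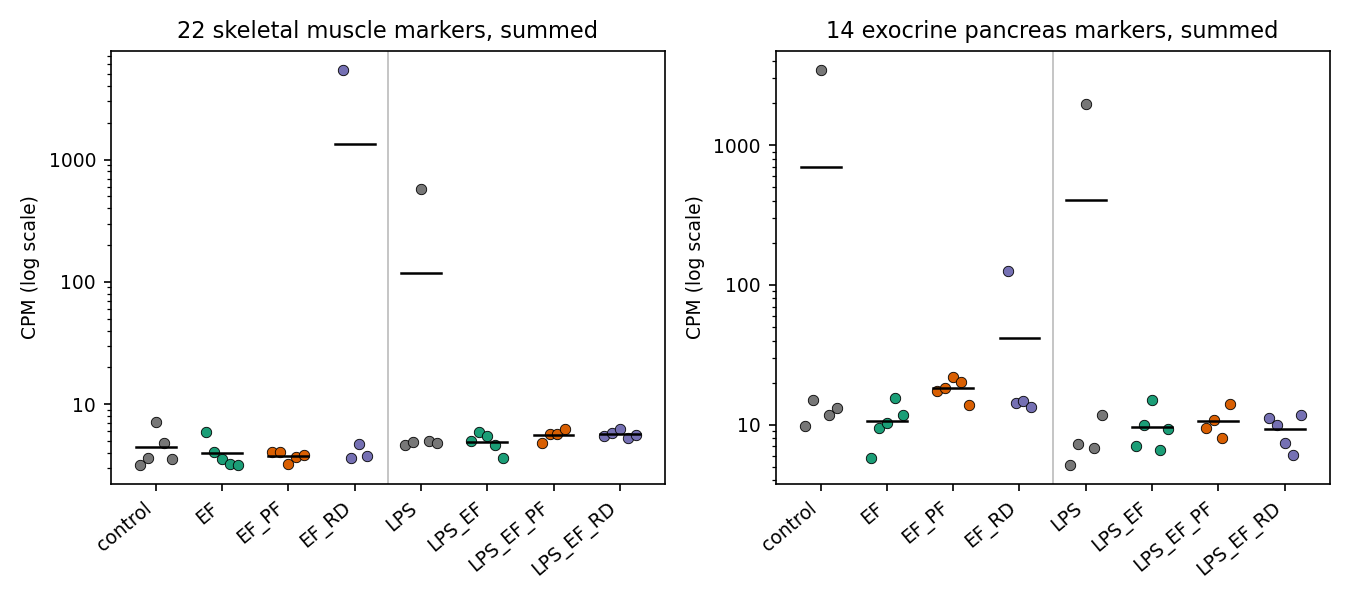
Summed levels of 22 skeletal muscle markers and of 14 exocrine pancreas markers in each of the 38 livers by group, as CPM on a log axis, where each point is a library. EF_RD 1 held 5350 CPM of muscle markers, against at most 4.75 CPM in the other EF_RD libraries, and control 5 held 3420 CPM of pancreas markers.

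PPARα and fatty acid oxidation genes went up with EF_RD, 3 of 30 called (15 higher and 1 lower adjusted over the list alone), with a median of 0.42. Endothelial markers went up with 0 of 15 called (6 adjusted over the list alone). Both lists had adjusted p = 2.15e-08, and adjusted p = 0.38 and 0.29 with an estimated correlation. Cholesterol synthesis had 2 higher of 25 (5 adjusted over the list alone) and AhR targets 2 of 7 (2 adjusted over the list alone). Their tests gave adjusted p = 1.81e-06 and 0.0446, and adjusted p = 0.729 and 0.29 with an estimated correlation. The AhR list call was lost in 5 of 9 omissions, with the highest adjusted p of 0.136 without control 6. Proliferation genes went down with 1 called of 28 (4 adjusted over the list alone), ER stress genes with 1 of 23 (9 adjusted over the list alone) and lipogenesis with 2 of 20 (6 adjusted over the list alone). The 3 lists had adjusted p = 3.82e-08, 1.12e-05 and 0.000458, and adjusted p = 0.532, 0.29 and 0.546 with an estimated correlation. Among the falls, Pdia6, a protein disulfide isomerase (−0.57 ± 0.15), lost its call in 7 omissions (highest adjusted p = 0.14), Pklr, pyruvate kinase (−1.08 ± 0.28), in 6 (0.158 without control 3) and Kcnj15 (−3.01 ± 0.73) in 5 (0.112 without control 7). Ltc4s (−2.59 ± 0.66) lost it in 7 (0.122 without EF_RD 1), Aldh1b1 (−1.41 ± 0.36) in 6 (0.151) and Hsd11b2 (−1.37 ± 0.35) in 6 (0.157). In all 225 genes were called, 127 higher and 98 lower, 89 and 21 of them at least 2-fold, and the higher share of 56.4% was 83.6% under total-count scaling. The count was 50 without EF_RD 1, 76 without control 3, 127 without control 4 and 134 without control 7. It was 54 without the 3 libraries with RNA of other tissues, 16 in a fit to only the 2 groups, 409 with DESeq2 and 788 with voom.

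Against EF, EF_RD was higher in Cyp26b1, which degrades retinoic acid (chromosome 4, 116261796 to 116278615), at 3.39 ± 1.57 against 0.388 ± 0.18 CPM (3.12 ± 0.44, adjusted p = 0.000617). Cholesterol synthesis was lower, 2 of 25 called (18 adjusted over the list alone), with a median of −0.62 (adjusted p = 2.02e-16, and adjusted p = 0.337 with an estimated correlation). Msmo1 (−1.4 ± 0.32) lost its call in 4 omissions and Fdps (−0.98 ± 0.25) in 8, at 0.102 and 0.131 without EF_RD 1. Endothelial markers were higher, 3 of 15 called (10 adjusted over the list alone, adjusted p = 1.13e-11, and adjusted p = 0.218 with an estimated correlation). The sinusoidal scavenger receptor Stab1 (1.25 ± 0.3) and the VEGF receptor Flt1 (0.8 ± 0.2) lost their calls in 8 and 6 omissions, at 0.115 and 0.167 without EF_RD 1. Lipogenesis and ER stress genes went down with 0 called (8 of 20 and 6 of 23 adjusted over the list alone). The list tests gave adjusted p = 7.98e-06 and 5.41e-05, and adjusted p = 0.337 each with an estimated correlation. Krt4 (6.19 ± 1.08), Pgam2 (4.66 ± 0.84) and Apobec2 (4.41 ± 0.8), of epithelium and muscle, were called at adjusted p = 0.00865, and without EF_RD 1 stood at 0.983, 0.567 and 0.762. In all 107 genes were called, 72 higher and 35 lower, and the higher share of 67.3% was 92.2% under total-count scaling. The count was 13 without EF_RD 1, 28 without EF 2, 49 without EF 3, 54 without EF 5, 57 without EF 4, 161 without EF_RD 2 and 312 without EF 1. It was 12 without the 3 libraries with RNA of other tissues, 0 in a fit to only the 2 groups and 221 with DESeq2.

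The extracts were then compared in LPS-injected rats. Cyp8b1 was higher with each than in LPS alone, where it was at 303 ± 74.2 CPM (n = 5). It reached 1010 ± 347 CPM in LPS_EF (n = 5, 1.74 ± 0.21, adjusted p = 2.7e-05), 791 ± 116 CPM in LPS_EF_PF (n = 4, 1.39 ± 0.22, adjusted p = 0.00227) and 756 ± 114 CPM in LPS_EF_RD (n = 5, 1.32 ± 0.21, adjusted p = 0.00602). The last call was lost without LPS 4 (adjusted p = 0.0625). In fits to only the groups compared the LPS_EF and LPS_EF_RD calls were lost (adjusted p = 0.0515 and 0.0838), with log2 fold changes that hardly moved. Ackr2, a chemokine-scavenging receptor (chromosome 8, 130526521 to 130543566), rose with LPS_EF from 2.47 ± 0.461 to 5.96 ± 2.05 CPM (1.27 ± 0.2, adjusted p = 0.00292). It lies close to the far more abundant Cyp8b1 (130548418 to 130550388, opposite strand), and reads were counted without a strand setting. The rise of Ackr2 was therefore not shown to be separate from that of Cyp8b1. Cyp1a1 rose with LPS_EF_PF from 0.601 ± 0.328 to 49.5 ± 19.1 CPM (6.36 ± 0.64, adjusted p = 2.94e-07) and Cyp1a2 from 400 ± 79.2 to 1258 ± 183 CPM (1.65 ± 0.26, adjusted p = 0.00227). A2m was not called in these 3 comparisons, at −0.57 (adjusted p = 0.84), −0.77 (0.949) and −1.01 (0.801).

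With LPS_EF, PPARα and fatty acid oxidation genes were higher than with LPS, 3 of 30 called (19 adjusted over the list alone), with a median of 0.62 (adjusted p = 7.63e-24, and adjusted p = 0.0439 with an estimated correlation). Decr1 rose from 80.9 ± 17.5 to 131 ± 13.3 CPM (0.7 ± 0.14, adjusted p = 0.0382). Its call was lost in 6 of 10 omissions, at most 0.16 without LPS 2. Cyp1a2 (1.25 ± 0.25, 7 omissions, 0.186), the carboxylesterase Ces2a (1.14 ± 0.24, 6 omissions, 0.174) and Glyatl2 (0.93 ± 0.19, 7 omissions, 0.234) were also higher, with these values without LPS_EF 7. Tcf24 (−1.09 ± 0.23, 9 omissions, 0.222), Cyp2c22 (−0.86 ± 0.18, 8 omissions, 0.16) and Car8 (−0.85 ± 0.18, 10 omissions, 0.16) were lower, with these values without LPS 2. Hepatocyte markers and CAR and PXR targets went up with 0 called (4 of 19, and 6 higher and 1 lower of 19, adjusted over the list alone), and bile acid genes with 1 of 23 (3 adjusted over the list alone). The 3 tests gave adjusted p = 1.36e-06, 5.23e-05 and 0.00166, and adjusted p = 0.238 each with an estimated correlation. LPS itself lowered these 3 lists as well as the PPARα list. A library with little LPS response, as LPS_EF 7 is, thus raises them in LPS_EF, and its share in these rises was not separated. In all 16 genes were called, 11 higher and 5 lower, and the higher share of 68.8% was 46.7% under total-count scaling. The count was 2 without LPS 2, LPS 4, LPS 5 or LPS_EF 5, 3 without LPS 1 or LPS_EF 7 and 9 without LPS_EF 6. It was 5 without the 2 libraries of low LPS response, 2 with the clock covariate, 90 with DESeq2 and 59 with voom.

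With LPS_EF_PF, AhR targets were higher than with LPS, 2 of 7 called (2, and 1 lower, adjusted over the list alone, adjusted p = 1.25e-05, and adjusted p = 0.00236 with an estimated correlation). Cyp2c11 fell from 718 ± 255 to 167 ± 85.3 CPM (−2.11 ± 0.4) and the growth factor Hdgf by 0.4 ± 0.08, both at adjusted p = 0.0227. These calls were lost in 6 and 7 of 9 omissions, at most 0.21 and 0.175 without LPS_EF_PF 3. Cholesterol synthesis and lipogenesis went down and mitochondrially encoded genes up with 0 called (17 of 25, 2 of 20 and 6 of 13 adjusted over the list alone). Their tests gave adjusted p = 2.57e-15, 7.67e-07 and 1.44e-09, and adjusted p = 0.234 each with an estimated correlation. In all 6 genes were called, 4 higher and 2 lower (66.7% higher, and 80% under total-count scaling). The sixth was the uncharacterised LOC102551973 (1.61, adjusted p = 0.0207), named after its values were seen. The count was 3 without LPS 2, LPS 4, LPS_EF_PF 3 or LPS_EF_PF 4 and 14 without LPS 3, and DESeq2 called 32 and voom 115. Against LPS_EF, 1 gene was called in LPS_EF_PF, Cyp1a1, higher by 3.93 ± 0.54 (adjusted p = 0.000365), and 2 without LPS_EF 5. DESeq2 gave Cyp1a1 a log2 fold change of 3.95 there but no adjusted p, and the 15 genes it called are others. Total-count scaling moved the median gene there from −0.003 to 0.112. PPARα genes and hepatocyte markers were lower in LPS_EF_PF than in LPS_EF with 0 called (5 of 30 and 3 of 19 adjusted over the list alone). Here the tests gave adjusted p = 6.95e-11 and 7.17e-07, and adjusted p = 0.255 each with an estimated correlation. LPS itself lowered both lists, and LPS_EF 7 showed little LPS response, but without it both list tests still passed.

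With LPS_EF_RD, 2 genes were called against LPS, Cyp8b1 and the carboxylesterase Ces2j (chromosome 19, 487723 to 495140). Ces2j rose from 8.87 ± 1.94 to 26.2 ± 10.3 CPM (1.56 ± 0.28, adjusted p = 0.0305), a call lost in 7 omissions, at most 0.204 without LPS 5. CAR and PXR targets and mitochondrially encoded genes went up with 0 called (6 of 19 and 2 of 13 adjusted over the list alone). The list tests gave adjusted p = 1.4e-05 and 8.41e-08, and adjusted p = 0.297 and 0.353 with an estimated correlation. The count was 0 without LPS 4, 1 without LPS 1, LPS 2, LPS 5, LPS_EF_RD 1, LPS_EF_RD 6 or LPS_EF_RD 8, 6 without LPS_EF_RD 4 and 9 without LPS_EF_RD 2, and DESeq2 called 16. Against LPS_EF, 0 genes were called in LPS_EF_RD by edgeR's test and by voom, with 412 at an unadjusted p under 0.05, and DESeq2 called 2. The smallest p-values were those of Ttll9 (3.95 ± 1.03), Decr1 (−0.59 ± 0.14) and Hadhb (−0.39 ± 0.1), each at adjusted p = 0.999. PPARα genes were lower as a list, 0 of 30 called (7 adjusted over the list alone), with a median of −0.40 (adjusted p = 7.47e-28, and adjusted p = 0.0202 with an estimated correlation). LPS itself lowered this list, and each group holds 1 library with little LPS response, LPS_EF 7 and LPS_EF_RD 6.

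**Figure D4:**
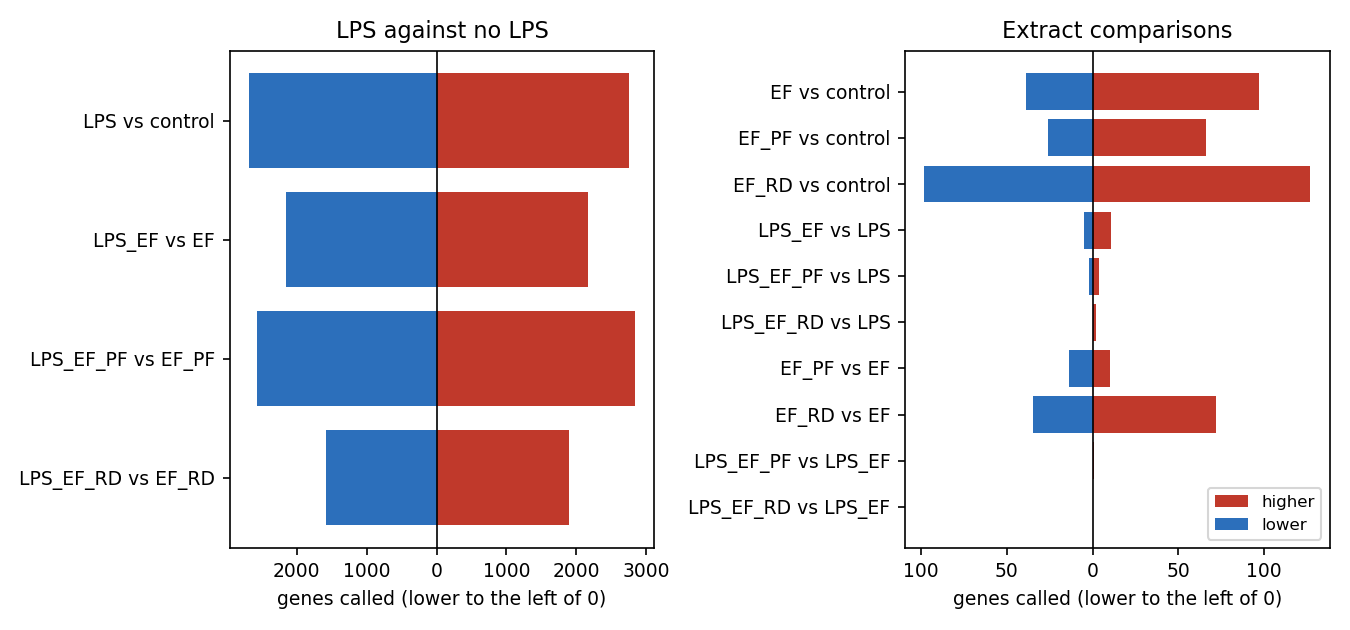
Numbers of genes called higher and lower at an adjusted p under 0.05 in each comparison, as bars from 0, with the LPS comparisons on the left and the extract comparisons on the right. LPS gave 3470 to 5435 calls in its 4 comparisons, and the extracts gave 92 to 225 against control and 2 to 16 against LPS.

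Whether an extract's effect differed with LPS was tested as an interaction. Cholesterol synthesis genes, which rose with LPS alone and with EF alone, were lower with both than the sum of the separate effects. For EF the interaction of Msmo1 was −2.47 ± 0.41, of Sqle −2.2 ± 0.38 and of Hmgcs1 −2.17 ± 0.37 (each adjusted p = 0.00909). Msmo1 had means of 128 ± 25.9 CPM in control, 556 ± 227 in EF, 504 ± 154 in LPS and 395 ± 147 in LPS_EF. Of 25 genes 8 were called negative (23 adjusted over the list alone), with a median of −1.27 (adjusted p = 4.28e-41, and adjusted p = 0.0198 with an estimated correlation). For EF_PF 9 were negative (25 adjusted over the list alone), with a median of −1.50 (adjusted p = 1.1e-61, and adjusted p = 0.00175 with an estimated correlation). Acat2 (−2.48 ± 0.46), Mvd (−2.26 ± 0.42), Msmo1 (−2.22 ± 0.43) and Mmab, of cobalamin metabolism (−1.42 ± 0.27), shared adjusted p = 0.0257. For EF_RD 0 were called (6 adjusted over the list alone), with a median of −0.64 (adjusted p = 8.66e-14, and adjusted p = 0.551 with an estimated correlation).

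**Figure D5:**
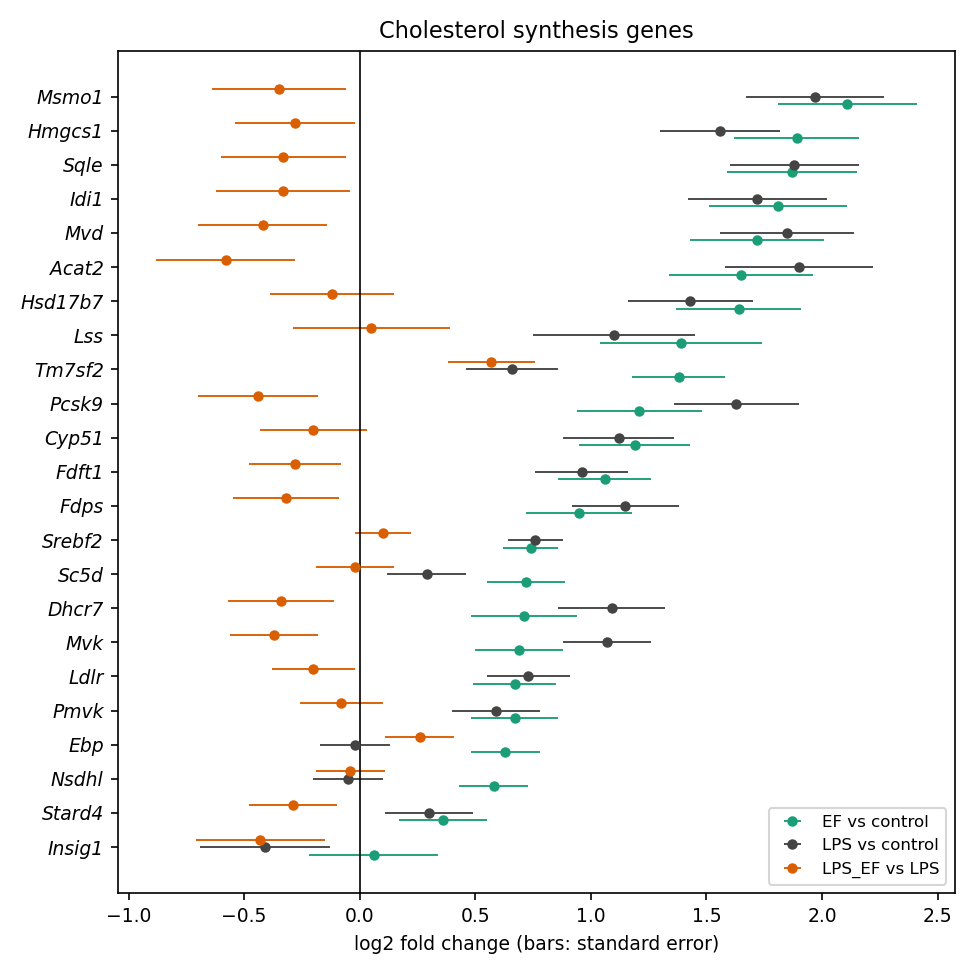
Log2 fold changes of 23 cholesterol synthesis genes for EF against control, LPS against control and LPS_EF against LPS, where each point is a gene and each bar its SE. The median over all 25 genes of the list was 1.06 for EF and 1.07 for LPS, and Hmgcs1 rose by 1.89 with EF.

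Among the other named interactions with EF, Idi1 (−2.14 ± 0.41) lost its call in 6 of 20 omissions and Mvd (−2.14 ± 0.4) in 5, at most 0.0848 and 0.0729 without EF 1. The named EF_PF interactions lost theirs in 8 or 9 of 19, with the highest adjusted p of 0.104 without LPS_EF_PF 6. Muscle genes led the EF_RD interaction, with Atp2a1 at −15.4 ± 2.54, Tnnt3 at −12.65 ± 2.22, Actn3 at −10.73 ± 1.99, Ttn at −10.61 ± 1.86 and Mylpf at −9.48 ± 1.72. Without EF_RD 1 their adjusted p was 0.544, 0.774, 0.735, 0.694 and 0.742, and the calls of Mylpf, Tnnt3 and Ttn were also lost without LPS 3. The gluconeogenesis list had an upward interaction with EF and the proliferation list with EF_RD, with 0 called (1 of 21 and 4 of 28 adjusted over the list alone). These tests gave adjusted p = 5.6e-09 and 4.94e-11, and adjusted p = 0.232 and 0.551 with an estimated correlation. A2m was not called, at −2.57 (adjusted p = 0.649), −1.28 (0.988) and −3.09 (0.492).

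In all 16 genes were called in the EF interaction, 12 in that of EF_PF and 19 in that of EF_RD, all negative. With the replicate number as a block these counts were 0, 0 and 2, and the 5 named EF interactions had adjusted p from 0.592 to 0.806. Without the 2 libraries with little LPS response the EF count was 5, and Idi1 and Mvd lost their calls. The EF count was 5 without control 4, EF 1, LPS 1, LPS_EF 5 or LPS_EF 7, 8 without LPS 4 or LPS_EF 4 and 10 without control 6, control 7 or LPS 5. The EF_PF count was 0 without control 4, control 6, EF_PF 1, LPS 1, LPS 4, LPS_EF_PF 1, LPS_EF_PF 3 or LPS_EF_PF 6. It was 5 without EF_PF 2, 19 without LPS_EF_PF 4 and 25 without LPS 3. The EF_RD count was 0 without EF_RD 1, 2 without LPS 3, 5 without control 3, 10 without control 4, control 6, control 7 or LPS_EF_RD 1 and 12 without LPS_EF_RD 2 or LPS_EF_RD 4. It was 32, 40 and 33 without EF_RD 2, EF_RD 3 and EF_RD 4, and 0 without the 3 libraries with RNA of other tissues.

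How far the extract responses overlapped was set against chance, since they share control libraries. In all 3 comparisons with control, 17 genes were called higher and 4 lower. Among them Cyp8b1 stood at 1.58, 1.63 and 1.75, the carboxylate transporter Slc13a3 at 1.39, 1.1 and 1.07 and Crem at −0.88, −0.98 and −0.92 for EF, EF_PF and EF_RD. EF and EF_PF shared 34 genes called higher and 6 lower. Independent lists would share 0.433 and 0.0686, simulated unchanged groups shared 0, and split controls gave a median of 6 and 0. Unchanged groups give almost no calls, so their overlap of 0 does not measure what shared controls add. Only the split controls address that, with fewer controls per comparison. EF and EF_RD shared 26 and 11 (0.833 and 0.258 for independent lists, 0 simulated, 4 and 1 with split controls). EF_PF and EF_RD shared 23 and 9 (0.567 and 0.172, 0 simulated, 5 and 0 with split controls). Across genes, which are not independent replicates, the fold changes of EF and EF_PF had r = 0.623 and a covariance of 0.141. In 10 simulations these were 0.491 and 0.052, and at the median of 20 assignments of split controls 0.008 and 0.002. For EF and EF_RD they were r = 0.44 and covariance 0.119 (0.462 and 0.053 simulated, 0.017 and 0.004 split), and for EF_PF and EF_RD 0.293 and 0.079 (0.466 and 0.054 simulated, −0.095 and −0.032 split). For both pairs with EF_RD, r lay under the simulated value and the covariance above it. On log2(TPM + 1) the r of the 3 pairs was 0.592, 0.561 and 0.518.

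Against the shared LPS group, LPS_EF and LPS_EF_PF had r = 0.704 and covariance 0.133 (0.458 and 0.047 simulated, 0.08 and 0.018 split) and shared 3 genes called higher, where independent lists would share 0.00298. LPS_EF and LPS_EF_RD had r = 0.778 and covariance 0.134 (0.487 and 0.047 simulated, 0.097 and 0.02 split). LPS_EF_PF and LPS_EF_RD had 0.674 and 0.113 (0.465 and 0.047 simulated, −0.006 and −0.001 split). On log2(TPM + 1) these r were 0.489, 0.75 and 0.51 in the same order. The last 2 pairs shared 1 gene each, Cyp8b1, where independent lists would share 0.00149 and 0.000541. With no shared libraries, the EF effect with and without LPS had r = 0.466 across genes, with 4 genes higher in both (0.0722 for independent lists) and 1 lower (0.0132). That of EF_PF had r = 0.394 with 4 higher in both (0.0179), and that of EF_RD r = 0.078 with 1 (0.0172). On log2(TPM + 1) these r were 0.333, 0.316 and 0.236. The LPS effect without extract correlated with that in EF at r = 0.783, in EF_PF at 0.819 and in EF_RD at 0.618 (0.843, 0.868 and 0.808 on log2(TPM + 1)). Genes called higher in both numbered 1723, 2085 and 1469 (403, 528 and 352 for independent lists), and lower in both 1482, 1765 and 1087 (389, 465 and 287).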

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

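Among the tests of explanations, those of the RNA of muscle and pancreas and of the low LPS response were chosen after the result was seen. A library apart from the rest of its group was sought in 176 combinations of a measure and a group, and 23 had one. Independent tests would give about 1 in 20 by chance, or 8.8. The measures share the same libraries and are not independent. The muscle and pancreas sums were added after their levels were seen, so part of the excess is built in.

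The cholesterol synthesis list went up with EF, EF_PF and EF_RD. For EF_RD 2 of 25 genes were called, and the list call was lost with an estimated correlation (adjusted p = 0.729). Among 126 splits of the libraries of each comparison with control, 1 split gave a median difference of the list as large, the real one, at 1.05, 0.912 and 0.43, and the highest others were 0.88, 0.687 and 0.404. Each comparison taken alone thus has a permutation p of 0.00794, the smallest these splits can give. For EF_RD the margin over the next split was small, 0.43 against 0.404. All these comparisons use the same control livers, so they are not independent results. The LPS rise of the list and its interactions use those livers too. Low levels of the list in the control livers would raise it in every comparison with control, and this was not tested. With a covariate for the daily rhythm the EF median was 1.026 beside 1.059, and without the libraries with RNA of other tissues it was 1.073, so neither is the whole cause. A response to the extract may remain, and feeding or body weight of the rats was not tested.

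Muscle genes rose in EF_RD and pancreas genes were lower in EF than in control. All 22 muscle markers were highest in EF_RD 1 among the 38 libraries, while the other EF_RD libraries held at most 4.75 CPM in sum beside 7.21 CPM in control, which argues against a rise in every EF_RD rat. All 14 pancreas markers were highest in control 5 among the control libraries. RNA of neighbouring tissue in these libraries is a candidate explanation, and whether it entered at dissection or later was not tested. The summed muscle markers were 5350 CPM in EF_RD 1 (others 3.65 to 4.75) and 573 CPM in LPS 3 (others 4.63 to 5.03), and the pancreas markers 3420 CPM in control 5 (9.87 to 15.1), 126 CPM in EF_RD 1 (13.3 to 14.7) and 1980 CPM in LPS 3 (5.19 to 11.8).

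LPS_EF 7 and LPS_EF_RD 6 showed less LPS response than the other LPS-injected livers in most measures. A2m was 5.84 CPM in LPS_EF 7 (others 84.2 to 223) and 6.9 CPM in LPS_EF_RD 6 (others 87.5 to 157), and Lcn2 was 0.265 CPM in LPS_EF_RD 6 (others 1030 to 2100). Lcn2 does not decide for LPS_EF 7. Its 42.4 CPM lay above 27 in LPS 2, 26.8 in LPS 4 and 31.9 in LPS_EF 3. It lay under 51.5 CPM in EF 1 without LPS and under 1110 to 1880 CPM in LPS_EF 4, 5 and 6. On a scale from 0 for the control mean to 1 for the LPS mean, taken as the median over 1625 genes that LPS changed at least 2-fold, LPS_EF 7 stood at 0.384 (others 0.887 to 1.04) and LPS_EF_RD 6 at 0.47, both under the highest library without LPS, EF 1 at 0.501. EF_RD 1 followed at 0.434, and the other libraries without LPS reached at most 0.213, so on this scale a response in part is not excluded. A swap with a library of a group without LPS would need a partner, and 0 such libraries had Cxcl9 above 185 CPM, the lowest of the other LPS-injected livers. LPS that did not act, or acted only in part, in these 2 rats is a candidate explanation, and a label taken from outside the series stays open.

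Other libraries apart from their group are given as values. On the same scale EF_RD 1 stood at 0.434 (others 0.081 to 0.092). Lcn2 was 1.57 CPM in EF_PF 1 (0.18 to 0.352) and 1090 CPM in LPS_EF_PF 6 (30.4 to 36.4). Levels on both sides of this gap also occurred within the LPS group. Lcn2 was at 26.8 and 27 CPM in LPS 4 and LPS 2 and at 955 to 2270 CPM in LPS 1, 3 and 5. In LPS_EF_PF 6 Cyp1a1 was 78.1 CPM (39.1 to 41.1) and Cyp1a2 1530 CPM (1160 to 1170). Cyp7a1 was 35.6 CPM in control 7 (102 to 156) and 178 CPM in EF_RD 3 (105 to 114). Cyp2c11 was 1990 CPM in control 7 (1440 to 1520) and 294 CPM in LPS_EF_PF 1 (120 to 132), and Alb 124000 CPM in LPS_EF_RD 6 (71100 to 83600). The total was 25400000 read pairs in EF_PF 1 (22300000 to 22900000) and 26800000 in EF_RD 4 (22700000 to 22900000).

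Genes called in the interaction test numbered 16 genes for EF, 12 for EF_PF and 19 for EF_RD. With the replicate number as a block these counts were 0, 0 and 2. Single omissions left 5 to 22, 0 to 25 and 0 to 40, with 0 for EF_RD without EF_RD 1, the library with RNA of muscle. For EF the named ones were Msmo1 (−2.47), Sqle (−2.2), Hmgcs1 (−2.17), Idi1 (−2.14) and Mvd (−2.14). For EF_PF they were Acat2 (−2.48), Mvd (−2.26), Msmo1 (−2.22) and Mmab (−1.42). For EF_RD they were Atp2a1 (−15.4), Tnnt3 (−12.65), Actn3 (−10.73), Ttn (−10.61) and Mylpf (−9.48).

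For each count of called genes, 100 splits of the same libraries into groups of the same sizes were refitted, the real one included. No other split called as many genes for LPS against control (5435 genes, 1 split as large, highest other 1915). The same was true of LPS with EF (4310, 1 split, 2929) and with EF_PF (5402, 1 split, 3462). It was also true of EF_PF against control (92, 1 split, 3) and LPS_EF against LPS (16, 1 split, 6). Each of these counts, taken alone, is unlikely by chance, at 1 of 100 splits, the smallest share these splits can give. Other splits reached the real count for LPS with EF_RD (3470, 3 splits, 4098). The split with 4098 put LPS_EF_RD 6, a library with little LPS response, with the EF_RD libraries. Other splits also reached it for LPS_EF_PF (6, 2 splits, 9) and LPS_EF_RD (2, 3 splits, 4) against LPS. The same holds for EF_PF against EF (24, 2 splits, 194) and LPS_EF_PF against LPS_EF (1, 4 splits, 1). For these comparisons chance is harder to exclude. No share of splits was adjusted for the number of comparisons. For the EF interaction (16, 4 splits, 58) and the EF_PF interaction (12, 4 splits, 12) the splits decide nothing. They exchanged extract labels among livers with the same LPS status, which removes the extract effects along with the interaction. The other splits called a median of 8 genes for EF and 0 for EF_PF.

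Chance cannot be excluded for the counts of EF against control (136, 6 splits as large, highest other 1318), EF_RD against control (225, 7 splits, 508) and EF_RD against EF (107, 17 splits, 753). The splits of the EF_RD interaction (19, 18 splits, 419) decide nothing either, since they also removed the extract effects. Its count was 0 without EF_RD 1, the library with RNA of muscle. For LPS_EF_RD against LPS_EF the splits decide nothing, since with 0 genes called all 100 splits reach that count (highest other 241). Splits that call several times the real count point to a structure of the samples other than the groups. The highest for EF exchanged control 3 and 7 with EF 1 and 2, and that of EF_RD against EF exchanged EF 1 and 2 with EF_RD 2 and 4. The highest splits of EF_PF against EF and of the EF interaction also passed the real count several times.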

How the results depend on the processing

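The alternatives without the 3 libraries with RNA of other tissues, without the 2 libraries with little LPS response and with a clock covariate were chosen after the data were seen. The 193 values of called named genes kept direction and call in all 193 with DESeq2 size factors, in 171 with DESeq2, in 168 without a filter on low counts, in 165 with voom, in 142 of 185 on log2(TPM + 1), in 145 of 185 on log2(TPM + 0.1), in 129 on log2(TPM + 1) without a filter, in 173 with the clock covariate and in 124 of 184 in a fit to only the groups compared. They did so in 105 of 140 without the 3 libraries, in 50 of 60 without the 2 libraries and in 1567 of 1987 fits with a library left out. The cause of a moved count was not tested, except that fits to only the groups compared, with libraries left out or without a filter use fewer samples or more genes. Depth limits genes with few counts, such as Gucy2c and Mmp3 in control.

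Counts that moved by over 1.5 times are given here by setting. DESeq2 called 273 genes with EF, 246 with EF_PF and 409 with EF_RD against control, 90, 32 and 16 with LPS_EF, LPS_EF_PF and LPS_EF_RD against LPS, and 173, 221, 15 and 2 for EF_PF and EF_RD against EF and LPS_EF_PF and LPS_EF_RD against LPS_EF. Its interactions had 29, 32 and 11 for EF, EF_PF and EF_RD. Voom called 87, 406 and 788 against control, 59, 115 and 6 against LPS, 330 for EF_RD against EF, 5704 for LPS_EF_RD against EF_RD, and 38 and 7 in the EF_PF and EF_RD interactions. Without a low-count filter the counts were 61 with EF_PF, 4 for LPS_EF against LPS, 5 and 196 for EF_PF and EF_RD against EF, and 42 in the EF_RD interaction. On log2(TPM + 1) they were 61 with EF_PF, 101 with EF_RD, 6 for LPS_EF against LPS, 2 and 10 against EF, 4 for LPS_EF_PF against LPS_EF and 0 in the EF_RD interaction. With a pseudocount of 0.1 they were 98 with EF_RD, 8 for LPS_EF against LPS, 1 and 12 against EF and 0 in the EF_RD interaction. On log2(TPM + 1) without a filter they were 71, 46 and 79 against control, 7 and 4 for LPS_EF and LPS_EF_RD against LPS, 4 and 14 against EF, 11 and 2 against LPS_EF and 1 in the EF_RD interaction. Fits to only the groups compared gave 35 and 16 with EF and EF_RD, 6 and 1 for LPS_EF and LPS_EF_RD against LPS, 1 and 0 against EF, 2 for LPS_EF_PF against LPS_EF, 2127 and 1692 for LPS with EF and EF_RD, and 9, 27 and 0 in the interactions.

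Without the 3 libraries with RNA of other tissues the counts were 54 with EF_RD, 14 for LPS_EF_PF against LPS, 12 for EF_RD against EF and 26 and 0 in the EF_PF and EF_RD interactions. Without the 2 libraries with little LPS response they were 5 and 1 for LPS_EF and LPS_EF_RD against LPS and 5 and 11 in the EF and EF_RD interactions. With the clock covariate they were 2 for LPS_EF against LPS, 1 for EF_PF against EF and 10 and 20 in the EF and EF_PF interactions.

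The labels do not say whether replicate numbers pair the livers, and the correlations leave it open. None of the 24 pairs of groups with at least 3 shared numbers had all correlations of same-numbered deviations over 0.1 (0 of 24), 25 of 80 same-numbered pairs exceeded 0.1, and 23 of 80 correlated best with their own number. Between EF and LPS, 4 of 5 same-numbered pairs exceeded 0.1 and 4 of 5 correlated best with their own number. The numbers to be had by chance were not computed. With the number as a block, 3565 genes were called for LPS against control, 3 and 1 for LPS_EF and LPS_EF_RD against LPS, 8 and 15 for EF_PF and EF_RD against EF, and 0, 0 and 2 in the interactions, and 137 of the 193 named values kept their call. The block turned the neutrophil list around for EF against control (adjusted p = 0.888) and in the EF interaction (0.679), the stellate list in that interaction (0.0383) and hepatocyte markers for LPS_EF_RD against LPS_EF (0.876).

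With each library left out in turn, counts ran from 4711 to 5419 for LPS, from 56 to 216 for EF, from 39 to 104 for EF_PF and from 50 to 276 for EF_RD. Against LPS they ran from 2 to 21 for LPS_EF, from 3 to 14 for LPS_EF_PF and from 0 to 9 for LPS_EF_RD, and against EF from 1 to 73 for EF_PF and from 13 to 312 for EF_RD. Against LPS_EF they ran from 1 to 2 for LPS_EF_PF and stayed at 0 for LPS_EF_RD. LPS within the arms called 3348 to 5047 genes with EF, 4571 to 5034 with EF_PF and 2288 to 4260 with EF_RD, and the interactions 5 to 22, 0 to 25 and 0 to 40.

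Few results that were called in the main fit or in the alternative changed direction. Apart from H19 and Neb in EF_RD against control these were lists, given here by adjusted p. Changes of direction without a call in either fit are not given. H19 stood at −0.29 with voom and −0.73 without the 3 libraries, and from −1.28 without EF_RD 1 to 7.66 without control 5. Neb ran from −0.14 without EF_RD 1 to 8.10 without EF_RD 4. Without the 3 libraries, the list of pancreas and other tissues turned for EF against control (0.884) and for LPS_EF (0.355), LPS_EF_PF (0.229) and LPS_EF_RD (0.00832) against LPS, and cholangiocyte markers turned for EF_RD against control (0.97). Left-out libraries turned the same pancreas list for LPS_EF (0.00399 to 0.636, turned without LPS 3) and LPS_EF_PF against LPS (0.00134 to 0.641, LPS 3). They also turned it for EF_RD against control (0.0351 to 0.871, control 5) and in the EF_PF interaction (0.0104 to 0.967, LPS 3 at 0.027). Ribosomal protein genes turned for EF against control (6.79e-05 to 0.642, EF 5 at 0.0187), EF_RD against EF (0.00172 to 0.896, EF 5) and LPS_EF_RD against LPS_EF (1.52e-09 to 0.51, LPS_EF_RD 6). In that last comparison erythroid markers (0.000769 to 0.985, LPS_EF 5) and cholesterol synthesis (2.56e-09 to 0.486, LPS_EF_RD 2 at 0.284) turned, and gluconeogenesis turned for LPS_EF_RD against LPS (0.000916 to 0.995, LPS_EF_RD 6).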

Other observations

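The ranges of clock genes were computed after the data were seen, and the list tests were not. Among LPS-injected rats, further lists went up in LPS_EF_PF, which differs from LPS in EF as well as PF, and each call was lost with an estimated correlation. Erythroid markers, genes of red blood cell formation, were higher in LPS_EF_PF than in LPS, with a median log2 difference of 1.29 over 13 genes (n = 4 and 5), and higher than in LPS_EF, with a median of 1.24. The list tests gave adjusted p = 1.1e-06 and 1.01e-09, and adjusted p = 0.309 and 0.255 with an estimated correlation. No single member was called, over all genes or adjusted over the list alone (0 of 13 in each). Proliferation genes were higher in LPS_EF_PF than in LPS_EF, with a median of 0.56 over 28 genes (adjusted p = 9.14e-10, and adjusted p = 0.255 with an estimated correlation; the test also passed without LPS_EF 7, a library with little LPS response), and lymphocyte markers higher than in LPS, with a median of 0.40 over 18 genes (adjusted p = 6.96e-06, and adjusted p = 0.309 with an estimated correlation). Against LPS_EF the lymphocyte list did not pass (adjusted p = 0.161). In both lists 0 members were called, also adjusted over the list alone.

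Clock genes varied widely between rats of the same group. Dbp, an output gene of the circadian clock, differed 17.5-fold between the lowest and highest control liver and 59.3-fold in LPS_EF, and Arntl, a core clock activator, differed 7.42-fold in control and 21.3-fold in LPS_EF_RD. The log2 ratio of Arntl to Dbp ran from −6.68 to 4.33 over the 38 livers. The time of day of collection is not given in the sources used here. Per1 differed 1.78-fold within control and 14.1-fold within LPS_EF_RD.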
